A study of Mus musculus with 6 samples.

How the data were processed

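Hippocampal microglia of 18-month-old male mice were sorted by BODIPY staining into LD-low and LD-high fractions, with 3 libraries per group, hippocampi of 3 mice pooled per sample and about 10000 cells sorted per sample, per the labels' protocols. Libraries were made with a Smart-seq kit for low input followed by tagmentation, per the labels' protocols. Such libraries do not mark the strand of a transcript, so reads of overlapping genes on opposite strands cannot be told apart. Reads were checked with FastQC 0.11.4, mapped to the mm9 build with STAR 2.5.1b, counted per gene by STAR and tested with DESeq2, per the submitters' processing notes and the series' design text. The gene annotation, the strand setting and the gene filter are not given in the sources used here.

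The deposited table holds a normalized signal per gene, that is, read counts divided by 1 size factor per library. Every deposited value was a whole multiple of 1 step per library: 100% of the values came out as whole reads within a tolerance of 0.01 reads. The steps correspond to size factors between 0.599 and 1.43, and recomputing the factors from the recovered reads by the median of ratios gave the same values. The table lists 14148 genes, each with at least 5 reads over the 6 libraries. Of these, 22 carry a date in place of a gene symbol, 2 of them the same date, and were left in as they stand without being named. Of the symbols, 12949 matched the GENCODE vM1 annotation of NCBIM37 (mm9), which gave the coordinates, transcript lengths and GC contents. Genes of families with near-identical copies, such as the histocompatibility genes, are uncertain where reads could map to more than 1 copy.

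Recovered reads per library ran from 15895576 to 38489448. A gene with 0 reads in a library could have had up to 3 reads there, a floor of 2.11 to 5.01 normalized counts depending on depth. Over the 3 LD-high libraries together the floor was 1.06 normalized counts, and folds against 0 reads use it. Intervals and floors cover counting error only, since reads were amplified and carry no molecular identifiers.

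The main test was limma 3.58.1 (R 4.3.3), with moderated variances that follow a mean-variance trend, on log2(normalized count + 1), so log2 changes are on that scale and understate the change of low genes. Genes with a value of at least 10 in at least 3 libraries were tested, which kept 11624 genes and left out 2524. P-values were 2-sided and adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold. The groups were compared without a term for the replicate number. The labels say that samples pool 3 mice each. The titles number the LD-low and LD-high samples alike, but nothing says whether samples with the same number came from the same pool. Nor is it said whether the pools hold different mice. If same-numbered samples did share a pool, the main test leaves that pairing out, and genes said not to have passed did not pass without it. If pools share mice, the p-values measure only the spread between these samples, which may be technical.

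Before the data were examined, 31 gene lists were fixed, and 28 had at least 5 tested members. They were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and with fry, each adjusted over the lists. The genes named in the text follow a rule fixed at the same time: the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 50 in a group and no overlap between groups, the 3 members of each list with the smallest p, and 20 genes always given. A gene named outside the rule is said to have been chosen after its values were seen, and so were Atp6v1c1 and H2-Eb1, which are named because their lists' counts rest on few genes. Cat, Kl, Rap1b, Rab5b, Rab7, Cd63, Slc33a1 and Tlr4 are genes the published study of these samples pointed to.

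The test was tested on simulated data drawn from the means and depths of the 6 libraries. Of 100 genes changed by 0.5 on the log2 scale 64% were called, of 100 genes changed by 1 unit 95%, and 8.21% of the calls were of genes that had not been changed, among 11611 genes. The genes changed by 0.5 or 1 were drawn from tested genes with a mean of at least 50 normalized counts. Their shares thus say nothing about lower genes. A simulated shift of the lysosome list by 0.3, above its real median of 0.14, was recovered and 0 of the other lists were called. Genes were drawn independently of each other, so the simulation cannot show how often lists of correlated genes are called in error.

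Alternatives were other pseudocounts (0.5 and 5), no filter and a filter of 50, TMM factors, quantile normalization, equal totals, limma without the trend, sample weights, another threshold, each library left out in turn, the replicate number as a block, and count tests on the recovered reads. Of the count tests, edgeR 4.0.16 (quasi-likelihood) called 377 genes and DESeq2 1.42.0 called 715. Corrections for transcript length and GC content and a count without marker genes of other cell types were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.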

Results

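RNA was sequenced from microglia, the resident macrophages of the brain, taken from the hippocampi of 18-month-old male C57BL/6 mice and sorted by their content of lipid droplets. Cells were stained with BODIPY, a dye that marks neutral lipid, and live cells carrying CD11b with low CD45, a usual gate for microglia, were sorted into a lipid droplet-low (LD-low) and a lipid droplet-high (LD-high) fraction of about 10000 cells per sample. There were 3 LD-low and 3 LD-high libraries, and each sample pooled the hippocampi of 3 mice. The LD-low libraries held 38489448, 23808102 and 27304709 reads in genes (replicates 1, 2 and 3), and the LD-high libraries held 36894483, 23622126 and 15895576. The number of genes with at least 1 read lay between 12987 and 13527 per library. Within groups, Pearson's r between the log2 values of pairs of libraries lay between 0.982 and 0.989. These correlations are across genes, which are not independent replicates. The first principal component held 40.7% of the variance and separated the groups, with LD-low libraries between -25.6 and -17.2 and LD-high libraries between 18.1 and 28.3. Each library was counted as 1 sample, since the labels list it as one and no 2 libraries held the same values.

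The comparison of LD-high with LD-low libraries asks how the transcripts of aged hippocampal microglia that hold many lipid droplets differ from those of microglia that hold few. Genes of lysosomes, endosomal trafficking, antioxidant defence, fatty acid oxidation and oxidative phosphorylation were shifted upward in LD-high microglia as lists, by camera with its preset correlation. Interferon-stimulated, inflammatory, antigen presentation and immediate early genes were shifted downward by the same test. None of the 28 lists tested passed camera with an estimated correlation, where 5 had an unadjusted p under 0.05 and the lowest value was an adjusted p = 0.229 with an estimated correlation. Of 11624 genes tested with limma, 390 differed, 178 of them higher and 212 lower in LD-high libraries. The balance depended on the processing: 118 were higher and 233 lower with equal totals, 382 and 333 with DESeq2, and, with corrections chosen after seeing the data, 446 and 184 for transcript length and 341 and 172 for GC content. Most changes were small: the median absolute log2 change was 0.34 for the genes that were higher and 0.58 for those that were lower, and 8 rose and 45 fell by more than 2-fold. The values of the 3 LD-high and 3 LD-low libraries did not overlap for 24.3% of the tested genes, where chance gives 10% on average. Because genes vary together across libraries, the share of a single split can lie far from that average by chance. Its spread was not computed. The count was 421 without LD-low replicate 1, 82 without LD-low replicate 2, 52 without LD-low replicate 3, 231 without LD-high replicate 1, 201 without LD-high replicate 2 and 90 without LD-high replicate 3. It was 252 with quantile normalization, 15 without a mean-variance trend, 715 with DESeq2 and 630 with the length correction. With the replicate number as a block it was 1090, and 28 of the 61 named genes that did not pass were then called. Whether the numbers pair the samples is not known.

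**Figure D1:**
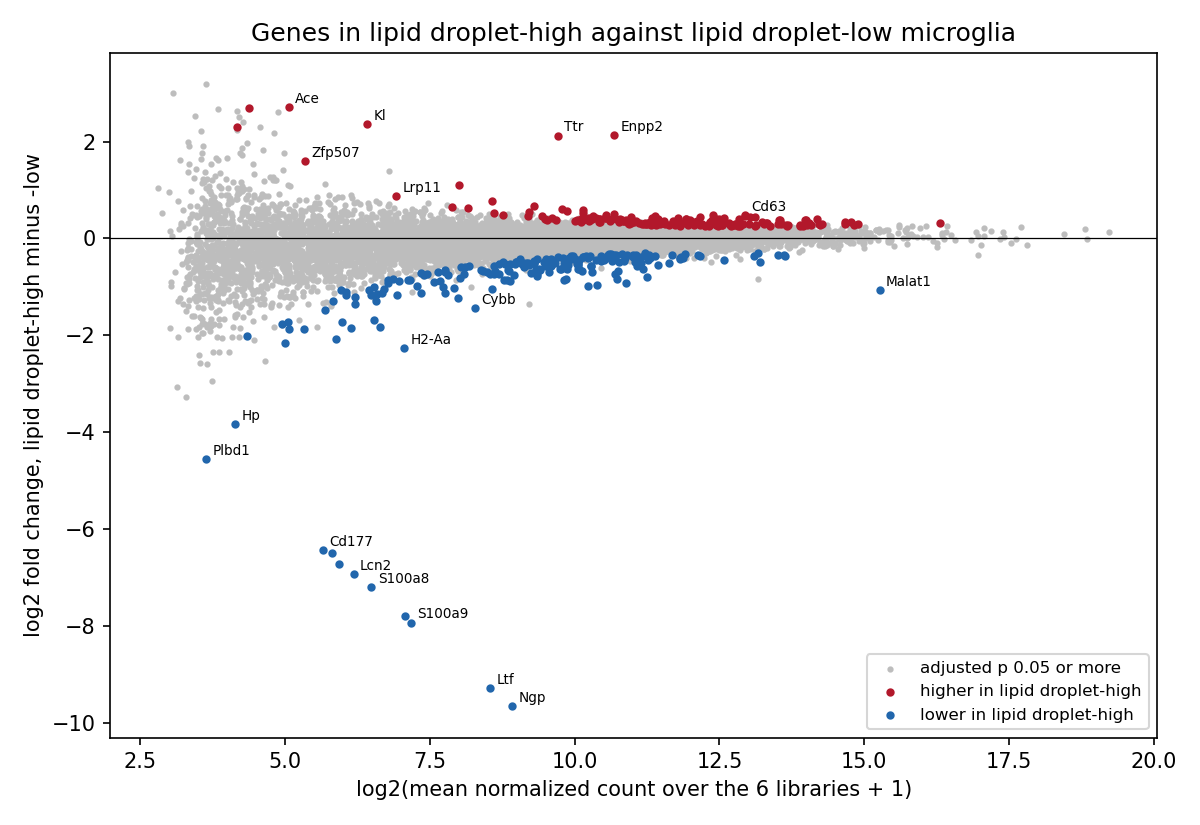
Each point is 1 of the 11624 genes tested, with its mean normalized count over the 6 libraries (log2 scale, horizontal) and its log2 change from LD-low to LD-high (vertical). The 178 red genes were higher and the 212 blue genes lower at an adjusted p under 0.05; most lie within 1 log2 unit of 0, and the blue points under -4 are neutrophil granule and related genes with 0 reads in the LD-high libraries, whose fitted change depends on the pseudocount.

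The lysosome and endosome lists passed camera upward with the preset correlation, while most of their members did not pass singly. Cd63, a tetraspanin of late endosomes and lysosomes (chromosome 10, 128345975 to 128349872), rose from 6557 ± 435 to 9169 ± 515 normalized counts (mean ± SD, n = 3 each), a log2 change of 0.48 ± 0.07 (SE) with an adjusted p of 0.00306. The small GTPases Rab5b, of early endosomes, and Rab7, of late endosomes, rose by 0.43 ± 0.08 and 0.36 ± 0.07 on the log2 scale (adjusted p 0.0145 and 0.0153). On the lysosome list, 4 of 34 members rose and 30 did not pass, with a median log2 change of 0.14. The 4 were Cd63 and the proton pump subunits Atp6v1a (0.40 ± 0.08), Atp6v1g1 (0.33 ± 0.07) and Atp6v1c1 (0.27 ± 0.06); 10 members rose when adjusted over the list alone. Camera gave the list an adjusted p of 3.5e-07, against an adjusted p = 0.400 with an estimated correlation and 0.121 with fry. On the endosome and phagosome trafficking list, 3 of 22 members rose (Rab5b, Rab7 and the retromer subunit Vps35, 0.33 ± 0.08) and 19 did not pass, with 7 higher when adjusted over the list alone. Its median was 0.14 and its camera adjusted p 1.98e-05, against an adjusted p = 0.229 with an estimated correlation. Cd63, Rab5b and Rab7 are genes that the study of these samples picked out, so their direction is no independent evidence. Cd63 was called in all 6 fits that left out 1 library, while Rab5b was lost in 2, Rab7 and Atp6v1a in 3 and Vps35 in 5, with the highest adjusted p without LD-low replicate 3 (0.0728, 0.0728, 0.0783 and 0.134), as were Atp6v1g1 in 4 and Atp6v1c1 in 5 (0.120 and 0.134). Oligodendrocyte and myelin markers moved in the same direction as these lists: the median of 6 members was 0.24, camera gave an adjusted p of 0.0121 and an adjusted p = 0.229 with an estimated correlation, and no member passed over all genes, with 3 higher when adjusted over the list alone. Choroid plexus epithelium markers, a list made after seeing the data, moved in this direction too (median 2.17 over 13 members, 6 of them picked from the called genes).

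The antioxidant defence, fatty acid oxidation and oxidative phosphorylation lists also passed camera upward with the preset correlation, with 3 members past the test singly. Cat, which encodes the peroxisomal enzyme that breaks down hydrogen peroxide (chromosome 2, 103294006 to 103325317), rose from 2995 ± 149 to 4037 ± 146 normalized counts (SD, n = 3 each), a log2 change of 0.43 ± 0.07 with an adjusted p of 0.00566, and was called in all 6 fits without 1 library. On the antioxidant defence list, 2 of 24 members rose, Cat and the peroxiredoxin Prdx1 (0.28 ± 0.07, lost in 5 of the 6 fits, highest adjusted p 0.175), and 22 did not pass, with 8 higher when adjusted over the list alone. The list's median was 0.19 and its camera adjusted p 1.41e-06, against an adjusted p = 0.229 with an estimated correlation. Cat too was picked out by the study. All 19 tested members of the fatty acid oxidation list lay above 0, with a median of 0.18. Only Hadhb, a subunit of the mitochondrial trifunctional protein, passed over all genes (0.32 ± 0.08, adjusted p 0.0345, lost in 4 of the 6 fits, highest adjusted p 0.148), and 6 members rose when adjusted over the list alone. Camera gave an adjusted p of 6.99e-06, against an adjusted p = 0.229 with an estimated correlation. Of 40 oxidative phosphorylation genes, 39 lay above 0 with a median of 0.13, and none passed in limma over all genes, while 7 rose when adjusted over the list alone. The smallest unadjusted p belonged to Sdha (0.24 ± 0.07, adjusted p 0.0582), and camera gave the list 1.41e-06, against an adjusted p = 0.229 with an estimated correlation. On the glycolysis and hypoxia list, 2 of 22 members rose, the glycolytic activator Pfkfb3 (0.34 ± 0.08) and the mitophagy receptor Bnip3 (0.42 ± 0.09), each lost in 4 of the 6 fits (highest adjusted p 0.154 and 0.119), with 3 higher when adjusted over the list alone. Its median was 0.07 and its camera adjusted p 0.0389, against an adjusted p = 0.400 with an estimated correlation, 0.218 with fry, 0.235 without LD-low replicate 3, 0.0736 without LD-high replicate 1 and 0.0876 without LD-high replicate 2. The myelin marker list (median 0.24) and the choroid plexus markers (median 2.17) moved in the same direction as these lists.

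Genes that build and coat lipid droplets did not pass the test between these fractions. The droplet coat gene Plin2 had 1226 ± 234 normalized counts in LD-low and 1376 ± 96 in LD-high libraries (SD, n = 3 each), a log2 change of 0.18 ± 0.12 with an adjusted p of 0.417. Plin3, another coat gene, had a log2 change of 0.50 ± 0.14 (adjusted p 0.0678), and the acyl-CoA synthetase Acsl1 one of 0.01 ± 0.08. None of the 21 tested members of the lipid droplet coat and storage list passed in limma over all genes or when adjusted over the list alone. The list's median was 0.08, its mean -0.06, and camera gave an adjusted p of 0.244 for an upward shift. Fry's test for change in either direction, which passed 20 of the 28 lists, gave this list an adjusted p of 0.0345. On the lipolysis and lipophagy list, Rab7 rose and 12 of 13 members did not pass, with a median of 0.12 and 1 member higher when adjusted over the list alone. Its camera adjusted p was 0.024, against an adjusted p = 0.287 with an estimated correlation, 0.0620 with fry and 0.0736 without LD-high replicate 1, and the myelin (median 0.24) and choroid plexus markers (median 2.17) moved in its direction. Lpl, which encodes the lipase that frees fatty acids from lipoproteins, fell by 0.99 on the log2 scale, from 1625 ± 642 to 789 ± 119 normalized counts (SD, n = 3 each, adjusted p 0.0157), and was lost only without LD-high replicate 3 (adjusted p 0.0571). The cholesterol biosynthesis list had a median of 0.01, with 0 of 19 members past the test and a camera adjusted p of 0.686. Of 13 cholesterol efflux and LXR target genes, the transporter Abca9 rose (0.33 ± 0.08, lost in 5 of the 6 fits without 1 library, highest adjusted p 0.205) and 12 did not pass, and camera gave 0.185. Slc33a1, picked out by the study, had a log2 change of -0.01 ± 0.10 (adjusted p 0.963).

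**Figure D2:**
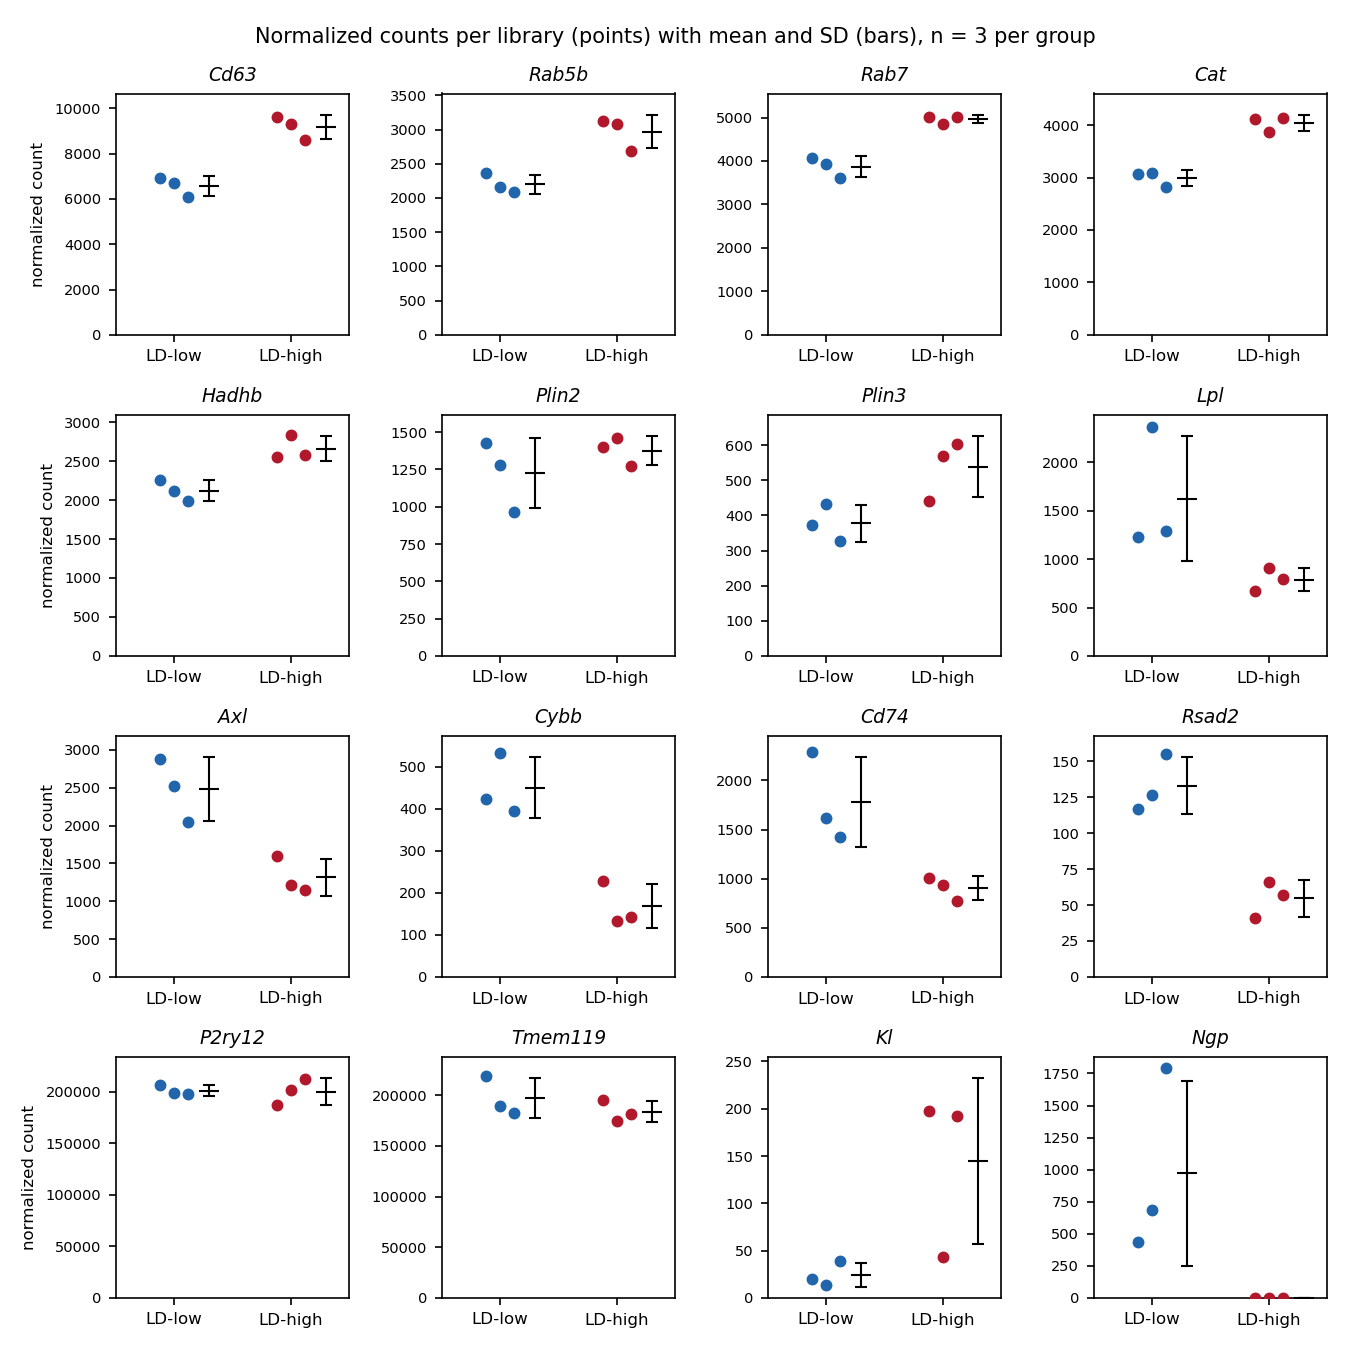
Each panel gives the normalized counts of 1 gene (vertical axis, from 0) in the 3 LD-low (blue) and 3 LD-high (red) libraries, with the mean and SD of each group as a bar beside the points. The groups do not overlap for Cd63 (6557 against 9169), Cat (2995 against 4037) or Cybb (450 against 168), and they overlap for Plin2 and P2ry12.

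The interferon-stimulated, antigen presentation and inflammatory lists passed camera downward with the preset correlation, while most of their members did not pass singly, and none of the 3 passed fry (adjusted p 0.0570, 0.218 and 0.0529). Of 28 interferon-stimulated genes, 3 fell and 25 did not pass: the antiviral gene Rsad2 fell by 1.29 on the log2 scale (133 ± 20 to 54.6 ± 12.7 normalized counts, SD, n = 3 each), Ifitm3 fell by 0.75 and the transcription factor gene Irf7 fell by 0.66. When adjusted over the list alone, 7 members fell and 1 rose. The list's median was -0.27 and its camera adjusted p 9.66e-05, against an adjusted p = 0.229 with an estimated correlation. On the antigen presentation list, 4 of 18 members fell, all of the MHC class II pathway: Cd74, the invariant chain, fell by 0.95 (adjusted p 0.00381), H2-Aa fell by 2.26, H2-Eb1 fell by 1.82 and H2-Ab1 fell by 0.88. When adjusted over the list alone, 5 members fell and 1 rose, and the class I genes H2-K1 and H2-D1, named after their values were seen, had log2 changes of -0.10 ± 0.08 and -0.17 ± 0.08. The list's median was -0.10 and its camera adjusted p 0.00783, against an adjusted p = 0.400 with an estimated correlation, 0.0640 without LD-low replicate 1 and 0.0669 without LD-high replicate 3. Of 22 inflammatory cytokine and NF-kB target genes, the chemokine gene Ccl12 fell by 0.63 and 21 did not pass, with 1 lower when adjusted over the list alone. The median was -0.17 and the camera adjusted p 0.00783, against an adjusted p = 0.229 with an estimated correlation and 0.0603 without LD-high replicate 2. The cytokine genes Tnf and Il1b had log2 changes of -0.13 ± 0.26 and 0.15 ± 0.22, and the receptor gene Tlr4, picked out by the study, one of -0.04 ± 0.09. Cd74 was called in all 6 fits that left out 1 library; Rsad2 was lost in 2, H2-Aa, H2-Ab1 and Ccl12 in 3, and Ifitm3 and Irf7 in 4, with the highest adjusted p at 0.182 for Irf7. Neutrophil genes moved in the same direction as these lists, with 6 of 7 markers lower (median -7.19). So did 7 of 9 border-associated macrophage markers (median -0.40), of which none passed. Of the LD-low libraries, replicate 1 held the most Cd74, H2-Aa and H2-Ab1 (2292, 378 and 890 normalized counts), Folr2 (77.2) and F13a1 (193). Replicate 3 held the most Ngp (1793), Rsad2 (155), Ifitm3 (298) and Ccl12 (936), and replicate 2 the most Irf7 (455).

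The immediate early and dissociation stress list passed camera downward as well: 3 of 25 members fell and 22 did not pass, with 4 lower when adjusted over the list alone. The transcription factor genes Klf4 and Klf2 fell by 1.73 and fell by 0.58 on the log2 scale, and Zfp36, whose product promotes mRNA decay, fell by 0.48 (adjusted p 0.0405, 0.0432 and 0.0179). These calls were lost in 5, 6 and 2 of the 6 fits without 1 library, with highest adjusted p values of 0.218, 0.173 and 0.0766. The list's median was -0.19 and its camera adjusted p 0.00756, against an adjusted p = 0.240 with an estimated correlation, 0.111 with fry and 0.0972 without LD-high replicate 2. The neutrophil markers (median -7.19) moved in the same direction.

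Homeostatic microglial genes did not pass the test, singly or as a list. P2ry12, a purinergic receptor gene used as a microglial marker, had 200733 ± 5127 normalized counts in LD-low and 200006 ± 12648 in LD-high libraries (SD, n = 3 each), a log2 change of -0.01 ± 0.09. Tmem119 and Cx3cr1 had log2 changes of -0.10 ± 0.10 and -0.34 ± 0.11 (adjusted p 0.615 and 0.115). None of the 20 homeostatic genes passed in limma over all genes or when adjusted over the list alone, the median was 0.00 with a mean of -0.01, and camera gave an adjusted p of 0.989. On the list of disease-associated microglial genes, members went both ways. Cd63 and Timp2 (0.30 ± 0.08, named after its value was seen) rose, while the receptor gene Axl fell by 0.91 (adjusted p 0.00243), Clec7a fell by 0.54, Lpl fell by 0.99 and Cd52, named after its value was seen, fell by 0.41; 20 members did not pass. When adjusted over the list alone, 6 rose and 7 fell. Camera gave an adjusted p of 0.327. Trem2, Tyrobp, Apoe and Cd68 did not pass, with log2 changes of 0.14 ± 0.07, 0.23 ± 0.08, -0.15 ± 0.13 and 0.06 ± 0.07. Axl was called in all 6 fits that left out 1 library, and Clec7a was lost only without LD-low replicate 2 (adjusted p 0.0571). The neutrophil markers (median -7.19) moved in the direction of the falls. Of the LD-low libraries, replicate 3 held the most Ngp (1793 normalized counts) but the least Axl and Clec7a (2042 and 1151). Lpl was lowest in replicate 1 (1224).

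Genes for making oxidants went both ways. Cybb, the catalytic subunit of the phagocyte NADPH oxidase (chromosome X, 9012378 to 9064897), fell by 1.45 on the log2 scale, from 450 ± 72 to 168 ± 53 normalized counts (SD, n = 3 each, adjusted p 0.00168), and was called in all 6 fits without 1 library. The xanthine oxidoreductase gene Xdh fell by 1.35, and Rap1b, a small GTPase gene that the study picked out, rose by 0.28 ± 0.07 (adjusted p 0.0370 and 0.0364, lost in 5 and 4 of the 6 fits, highest adjusted p 0.189 and 0.160). The other 8 of 11 oxidant production genes did not pass, 2 rose and 2 fell when adjusted over the list alone, and camera gave an adjusted p of 0.489 for an upward shift, with a median of 0.07 and a mean of -0.17. Among 25 phagocytic and complement receptor genes, Dock2 rose (0.31 ± 0.07), Axl fell by 0.91, the complement gene C3 fell by 1.14 and 22 did not pass, with 2 higher and 2 lower when adjusted over the list alone and a camera adjusted p of 0.501. Dock2 and C3 were lost in 5 and 4 of the 6 fits without 1 library (highest adjusted p 0.116 and 0.154). The neutrophil markers (median -7.19) moved in the direction of the falls of Cybb, Xdh, Axl and C3. Of the LD-low libraries, replicate 3 held the most Ngp (1793 normalized counts) but the least Cybb, Xdh and Axl (396, 70.6 and 2042). C3 was highest there (176).

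**Figure D3:**
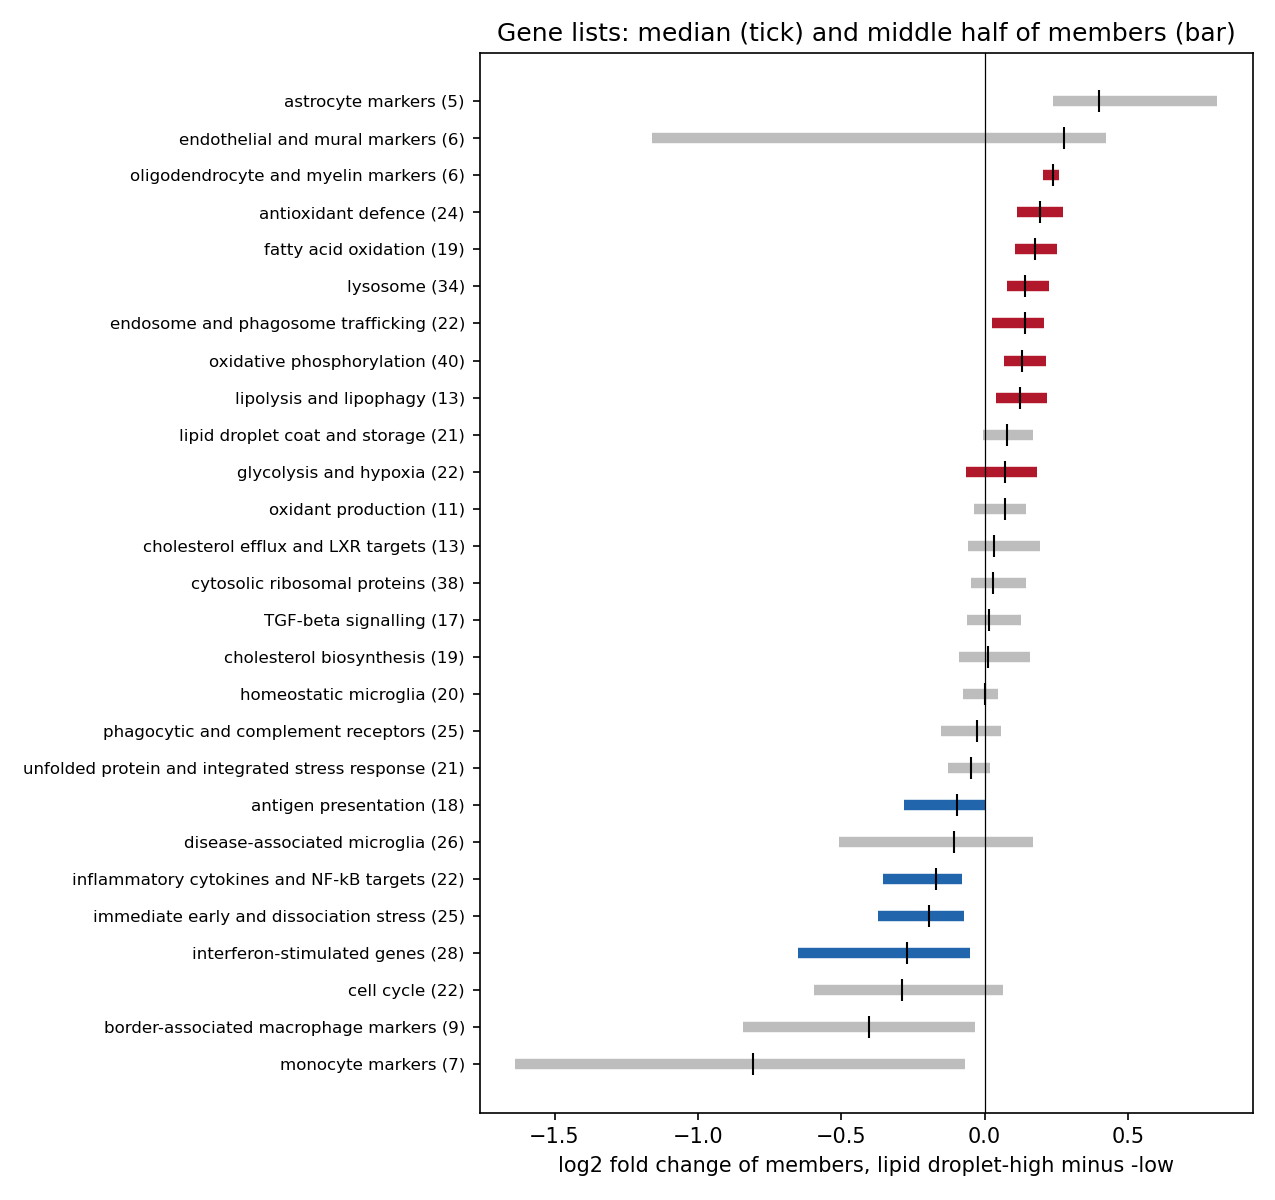
Each line is 1 list with the number of tested members in brackets; the tick gives the median and the bar the range from the lower to the upper quartile of the members' log2 changes from LD-low to LD-high. Red lists passed camera upward and blue lists downward at an adjusted p under 0.05 with the preset correlation, grey lists did not pass, and the neutrophil list (median -7.19) lies outside the axis and is left out.

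The genes with the largest falls were granule and secretory genes of neutrophils. Ngp, a neutrophil granule protein gene (chromosome 9, 110322254 to 110325514), had 971 ± 723 normalized counts in LD-low libraries (SD, n = 3) and 0 reads in all LD-high libraries, and was at least 917-fold higher in LD-low. In the same way Ltf was at least 703-fold, S100a9 at least 270-fold, Chil3 at least 253-fold, S100a8 at least 168-fold, Lcn2 at least 136-fold, Camp at least 113-fold, Anxa1 at least 105-fold and Cd177 at least 93.6-fold higher in LD-low libraries. Without LD-low replicate 3, which held more of these transcripts than the other LD-low libraries (Ngp at 435, 684 and 1793 normalized counts in replicates 1, 2 and 3), the bounds were 529-fold for Ngp, 398-fold for Ltf, 157-fold for S100a9, 140-fold for Chil3, 88.9-fold for S100a8, 78.0-fold for Lcn2, 73.4-fold for Camp, 57.4-fold for Anxa1 and 55.7-fold for Cd177. These folds are set against a floor of 3 reads over the LD-high group and cover counting error only. The adjusted p values of these 9 genes ran from 3.45e-08 to 0.000216, and all were called in each of the 6 fits without 1 library. On the neutrophil list, 6 of 7 tested members fell, also when adjusted over the list alone. The seventh member, the colony-stimulating factor receptor gene Csf3r, named after its value was seen, did not pass (log2 change -0.04, adjusted p 0.770). The list's median was -7.19, or -7.40 with the genes at 0 set to their bound, and camera gave an adjusted p of 2.55e-18, against an adjusted p = 0.229 with an estimated correlation.

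Ace and Kl rose several-fold in LD-high libraries. Kl, which encodes klotho (chromosome 5, 151755182 to 151796384), rose from 24.2 ± 13.1 to 145 ± 87 normalized counts (SD, n = 3 each), a log2 change of 2.37 ± 0.50 with an adjusted p of 0.0248. Ace, the angiotensin-converting enzyme gene, rose from 8.34 ± 5.25 to 56.9 ± 21.3, a log2 change of 2.72 ± 0.52 with an adjusted p of 0.0158. Kl was lost without LD-low replicate 2, LD-high replicate 1 or LD-high replicate 3 (adjusted p 0.0934, 0.0744 and 0.0960), and Ace without LD-high replicate 1 or 3 (0.0580 and 0.0734). Without LD-high replicate 2 the log2 change of Kl was 3.08. Kl was picked out by the study. Ttr and Enpp2, abundant genes of the choroid plexus that were named after their values were seen, rose as well, by 2.12 ± 0.50 and 2.13 ± 0.45 on the log2 scale, and were each lost in 3 of the 6 fits without 1 library (highest adjusted p 0.105 and 0.0888). The log2 change of Ttr was 1.36 without LD-low replicate 2 and 2.73 without LD-low replicate 3, and that of Enpp2 was 2.73 without LD-high replicate 2. Among called genes with a mean of at least 50 normalized counts in a group and no overlap between the groups, which leaves out Ttr and Enpp2, the 8 largest rises after Ace and Kl were those of Zfp507 (1.60 ± 0.40), 2900026A02Rik (1.11 ± 0.16), the lipoprotein receptor-related gene Lrp11 (0.87 ± 0.22), Rapsn (0.78 ± 0.12), Arhgap19 (0.66 ± 0.11), the potassium channel gene Kcnj9 (0.64 ± 0.15), Nbl1 (0.64 ± 0.15) and the serine synthesis gene Psat1 (0.61 ± 0.14). Of these, 2900026A02Rik and Rapsn were called in all 6 fits without 1 library, Arhgap19 was lost in 1, Zfp507 and Psat1 in 4, Lrp11 in 5, and Kcnj9 and Nbl1 in 6.

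The remaining lists with at least 5 tested members did not pass camera. The lymphocyte, neuron and erythroid lists had too few tested members for it. Cytosolic ribosomal protein genes (38 members, median 0.03, adjusted p 0.279), unfolded protein and integrated stress response genes (21 members, median -0.05, adjusted p 0.427), cell cycle genes (22 members, median -0.29, adjusted p 0.185) and TGF-beta signalling genes (17 members, median 0.02, adjusted p 0.489) had no member past the limma test over all genes or when adjusted over the list alone. The same held for 9 border-associated macrophage markers (median -0.40, adjusted p 0.200). Of 7 monocyte markers (median -0.81, adjusted p 0.152), Ace rose and Chil3 and Cd44 fell, Cd44 by 1.48 ± 0.37 on the log2 scale and lost in 5 of the 6 fits without 1 library (highest adjusted p 0.178), with 2 higher and 3 lower when adjusted over the list alone. The 5 astrocyte markers had a median of 0.40 and a camera adjusted p of 0.0942, and the 6 endothelial and mural markers a median of 0.28 and a mean of -0.47 with a camera adjusted p of 0.675 for an upward shift. No member of these passed over all genes, and 2 astrocyte markers rose and 1 endothelial marker rose and 1 fell when adjusted over the list alone. Of 4 lymphocyte markers, Il7r fell by 0.45 (adjusted p 0.0291, also when adjusted over the list alone, lost in 5 of the 6 fits, highest adjusted p 0.139). The 2 tested neuron markers, Camk2a and Rbfox3, did not pass (0.76 ± 0.32 and 0.49 ± 0.64), and no erythroid marker was tested. Without the marker genes of other cell types, a set that was completed after seeing the data, 368 genes differed, 170 higher and 198 lower.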

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

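The count of 390 genes (178 higher, 212 lower) moved by less than 1.5 times, to between 351 and 513, with other pseudocounts, no filter or a filter of 50, TMM factors, equal totals, sample weights, edgeR, the GC correction and the removal of other cell types' markers. Beyond that, quantile normalization gave 252 genes with 108 higher, limma without a trend 15 (1 higher, 14 lower), DESeq2 715 (382 higher, 333 lower), an adjusted p under 0.1 819 (412 higher, 407 lower), and the length correction, chosen after seeing the data as was the GC correction, 630 with 446 higher. Equal totals gave 118 higher genes (33.6% of its calls, against 45.6% of the 390), the GC correction 341 (66.5%), and the length correction's share was 70.8%. The cause of these differences was not tested, except that the threshold of 0.1 is wider. All 390 genes kept their direction wherever they were measured under these alternatives, and DESeq2 called 385 of them, edgeR 368 and limma without a trend 14. The kept direction is weak support, since 388 of them did not overlap between groups. Changing the filter or the trend also leaves the log2 change itself as it was. Leaving out 1 library in turn gave 52 to 421 genes, 17 to 212 higher and 35 to 209 lower, with fewer samples in each fit. Of the 51 named genes that were called, 16 were called in all 6 of these fits, and all kept their direction under the alternatives with all 6 libraries, with the same limit. Quantile normalization still called 39 of the 51, equal totals 47 and limma without a trend 9. Leaving out 1 library cannot turn a gene whose groups do not overlap. With the replicate number as a replicate block, limma called 1090 genes (560 higher, 530 lower), edgeR 1065 (533 higher, 532 lower) and DESeq2 811 (468 higher, 343 lower), and limma's calls included all 390. Under the block, 28 of the 61 named genes that had not passed were called by limma (26 by edgeR, 21 by DESeq2). Without the block, DESeq2 called 15 of the 61, edgeR 1, the length correction 16 and the GC correction 9. Same-numbered LD-low and LD-high samples had correlated deviations of 0.161, 0.132 and 0.064, so 1 pair lay under 0.1, and every sample correlated best with its own number, which is a hint from the data and not from the design. The splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05: 1 of them, the real one, gave 390 genes, and the highest of the others gave 1. Of the gene lists, 13 passed, 10 to 15 over the other alternatives and 10 to 14 without 1 library, but 0 passed with an estimated correlation and 8 with fry, and the cause was not tested. Of the 13, fry did not pass lipolysis and lipophagy (adjusted p 0.0620), lysosome (0.121), glycolysis and hypoxia (0.218), interferon-stimulated (0.0570), inflammatory (0.0529), antigen presentation (0.218) and immediate early genes (0.111); fry asks whether members move on balance in 1 direction, not whether they differ from other genes, and it passed the monocyte (0.0295) and astrocyte markers (0.0329) besides. A filter of 50 ended the calls of lipolysis (0.0502) and glycolysis (0.0755), quantile normalization those of lipolysis (0.0718) and glycolysis (0.221), limma without a trend those of glycolysis (0.0839) and antigen presentation (0.0671), sample weights (0.0799), the length correction (0.0716) and the GC correction (0.0508) that of glycolysis, and no filter that of the myelin markers (0.152). No list changed direction. Of the named genes that did not pass, 9 changed sign, all close to 0 or at low counts: Acsl1 to -0.022 with quantile normalization and -0.036 with equal totals, P2ry12 to 0.0024 with sample weights, 0.034 with the length and 0.036 with the GC correction, Cd68 to -0.011 and Tnf to 0.067 with quantile normalization, Tlr4 to 0.0053 with the GC correction, Slc33a1 to 0.027 with the length and 0.0050 with the GC correction, and Lck to 0.21 with edgeR and 0.27 with DESeq2. Without 1 library in turn, Acsl1 ran from -0.052 to 0.073, P2ry12 from -0.050 to 0.042, Tlr4 from -0.11 to 0.055, Il1b from -0.037 to 0.29, Slc33a1 from -0.083 to 0.094, Lck from -1.003 to 0.87 and Rbfox3 from -0.15 to 0.98; the cause was not tested. Depth limits the low genes: at 15895576 reads, 3 reads in LD-high replicate 3 correspond to 5.01 normalized counts.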

Other observations

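The lists and tests in this part were all chosen after the data were seen, and the outcomes that would count for or against GC content and nuclear RNA were set before those results were computed. On a peroxisome list, 4 of 41 members rose and 37 did not pass: Cat, the import receptor gene Pex7 (0.47 ± 0.11, log2 change ± SE), the beta-oxidation gene Hsd17b4 (0.40 ± 0.07) and the sterol carrier gene Scp2 (0.30 ± 0.07). The median was 0.07 and the camera adjusted p over the 7 added lists 0.00103, against an adjusted p = 0.0416 with an estimated correlation. These values are no independent support, since the list was made after called members such as Cat were seen. They are adjusted over the 7 added lists only, whereas 0 of the 28 fixed lists passed with an estimated correlation. On an autophagy and mitophagy list, 7 of 39 members rose and 32 did not pass, with a median of 0.13. Among the 7 were the autophagosome gene Map1lc3b (0.33 ± 0.07), the mitophagy receptor genes Bnip3 (0.42 ± 0.09), Bnip3l (0.28 ± 0.07) and Fundc1 (0.38 ± 0.08), and the mitochondrial fission genes Fis1 (0.34 ± 0.09) and Mff (0.29 ± 0.07). Camera gave 9.09e-07, and an adjusted p = 0.0416 with an estimated correlation, with the same limits. Of 16 proton pump (V-ATPase) subunit genes, Atp6v1a, Atp6v1c1 and Atp6v1g1 rose, Tcirg1 fell by 0.37 and 12 did not pass (camera 0.000342, adjusted p = 0.163 with an estimated correlation). Myelin markers (median 0.24, camera adjusted p 0.0121, adjusted p = 0.229 with an estimated correlation) and choroid plexus markers (median 2.17) moved in the same direction as these 3 lists. The calls depended on single libraries: Hsd17b4 was lost in 2 of the 6 fits without 1 library, Tcirg1 in 3, Bnip3 and Fundc1 in 4, Pex7, Map1lc3b, Bnip3l and Mff in 5, and Scp2 and Fis1 in 6, with the highest adjusted p at 0.178 for Fis1.

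Transcripts of neutrophil granules were far lower in LD-high libraries: all 11 tested members of an extended list fell, 10 of them with 0 LD-high reads and the other, Hp, with 6 and lost in 4 of the 6 fits without 1 library (highest adjusted p 0.188), most of them picked from the called genes. Shallower sequencing of the LD-high libraries is argued against, since at the lowest LD-low level the smallest number of reads expected in an LD-high library for any of the 10 genes was 10.4. A candidate explanation is a small number of cells of the neutrophil lineage in the LD-low sort, although the gate on low CD45 would be set to leave neutrophils out. It predicts that neutrophil genes too low to be tested differ too, and 5 of these (Fcnb, Mmp8, Mmp9, Pglyrp1 and Hdc) had 295 LD-low and 8 LD-high reads, a ratio per size factor of 30.5 (15.3 to 71.3, exact 95% interval for counting error) that was 17.2 (8.44 to 40.8) without LD-low replicate 3 and 128 (22.9 to 5092) without LD-high replicate 1, with the abundant S100a8 and S100a9 at 178 and 286 normalized counts in LD-low libraries. The prediction was written and the 5 genes were picked after the data were seen, so the ratio is no independent check. Of the untested members of the fixed neutrophil list, only Mmp8 and Mmp9 were among them. Transcription of the granule genes by LD-low microglia themselves cannot be told apart from cells of the neutrophil lineage: the genes varied 3.24-fold between LD-low libraries (geometric mean), and reads are not assigned to cells.

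Kl and Ace belong to a wider group: of 13 tested choroid plexus epithelium markers, 12 lay above 0 and 6 rose (Ttr, Enpp2, Kl, Ace, Slc13a4 and Sulf1), with a median of 2.17; those 6 were picked from the called genes, and Ttr, Enpp2 and Slc13a4 were lost in 3 and Sulf1 in 6 of the 6 fits without 1 library (highest adjusted p 0.105, 0.0888, 0.0743 and 0.134). The deviations of Kl within groups followed the mean of the other tested markers (Pearson's r 0.977 and Spearman's rho 1 over the 6 libraries, 1-sided exact permutation p = 0.0278 for both, the smallest that 36 arrangements can give, and r 0.950 without the 2 libraries farthest from the median). Within groups, Kl thus varied with these markers. A separate rise of Kl shared by all LD-high libraries would leave these deviations unchanged, so the test cannot tell whether there was one. The log2 change of Kl was 2.37 ± 0.50, and the median of the other tested markers was 2.15. A candidate explanation is choroid plexus material in the sorts, more of it in LD-high samples, although the gate on CD11b would leave epithelium out. The markers varied together within groups, with a mean pairwise correlation of 0.573 against 0.123 at the 95th percentile of random lists matched on expression. Genes that share any source would do so, and thus the correlation cannot tell such material from uptake or transcription by microglia. Ttr, a dominant transcript of that epithelium, had 358 ± 272 normalized counts in LD-low and 1319 ± 615 in LD-high libraries (SD), and Enpp2 had 621 ± 407 and 2664 ± 1440. These counts are not scaled to transcript length, so the lower counts of Ttr do not show that it had fewer transcripts. Whether part of the Enpp2 reads had another source was not tested. Uptake or transcription by microglia with many droplets stays open and was not tested.

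Of 6 nuclear-retained non-coding RNAs 4 fell in LD-high libraries (Malat1 by 1.06 ± 0.13 on the log2 scale, Neat1, Ftx and Kcnq1ot1, which lies antisense to a coding gene) and of 52 chromatin regulators 14 fell, among them Ash1l, Bptf and Kmt2a, 38 did not pass and 8 lay above 0 (camera 7.79e-12, adjusted p = 0.120 with an estimated correlation), while the neutrophil markers (median -7.19) moved in the direction of the falls. A length correction did not remove the fall: the median of the 50 members of both lists with a known length was -0.19 before and -0.14 after it, with a camera p of 4.39e-10. Nor did a GC correction, after which the median of the 47 chromatin regulators with a known GC content went from -0.18 to -0.13 with a camera p of 2.03e-10. Both lists were made after the data were seen, so a median below 0 is partly built in. These camera p values are therefore no independent support, and the corrections cannot exclude length or GC content as a cause. A smaller share of nuclear RNA in the LD-high libraries cannot be told apart from a change in the cells: of the tested nuclear RNAs that were not called, 0 lay above 0 by more than their standard error, but there are only 2 (Tug1 -0.02 ± 0.07, Jpx -0.10 ± 0.38). The outcome set beforehand in favour of a smaller share was not met either, as it asked for more such RNAs and a larger fall of each. Tug1 had 6144 ± 324 normalized counts in LD-low and 6045 ± 461 in LD-high libraries (SD). Of the fits without 1 library, Malat1 was called in all 6, Neat1 was lost in 3, Kcnq1ot1 in 4 and Ftx in 5, and of the 14 chromatin regulators Bptf, Chd2 and Chd7 were called in all 6 and the other 11 lost in 1 to 4; a lower transcription of these genes in microglia with many droplets stays open as an untested hypothesis that these values may reflect.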
